A study of Mus musculus with 9 samples.

How the data were processed

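RNA of sorted CD45.1+ LKS+ marrow cells from C57BL/6 mice aged 8 weeks was measured on 9 Affymetrix Mouse Genome 430 2.0 arrays, 3 per group. The values used here are the authors' deposited normalized intensities, 1 value per probe set and array, on a linear scale. Per the series' design text, RNA was amplified over 2 cycles before labelling and hybridisation. The same text says that signals were normalized with the Affymetrix Microarray Analysis Software 5.0. The deposited table itself raises a doubt about that step, since 51.64% of probe sets (23255 of 45037) hold exactly equal values in at least 2 arrays, as a summary across arrays can give, and the scaling of the arrays was therefore varied below. No other step is given in the sources used here. Amplification over 2 cycles favours transcript ends near the poly(A) tail, so probe sets of a gene that lie far from that end can read low. Intensities ran from 1.61 to 13899; the 75th percentile lay between 115 and 119 in the day 14 arrays and between 127 and 130 in the other 6, so small changes at day 14 depend on the scaling.

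Each array was placed in its group by its sample labels, which number the replicates within each group and call them biological. Probe sets were named through the platform annotation: 34945 had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 symbol named a gene. Symbols were compared with a RefSeq gene table of assembly GRCm38.p6, used for names alone; 0 symbols changed, and for 204 gene identifiers the table held no current symbol. Of 18193 genes so named, 9010 had more than 1 probe set, and the probe set with the highest mean log2 intensity over the 9 arrays stood for the gene. Values below the 20th percentile of the table (5.81) were raised to it before log2 was taken. A gene was tested if its probe set lay above the 40th percentile of its array, an intensity of 14.1 to 15.2, in at least 3 arrays, which left 12652 genes and removed 5541. Where a probe set lay below that percentile in every array of a group, its change is given as a lower bound, the mean of the brighter group against the higher of the percentile and the value in each array of the dimmer group.

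Group differences were tested with limma 3.58.1 in R 4.3.3, with 1 linear model over all 9 arrays, no covariates and moderated two-sided tests, because 3 arrays per group estimate the spread poorly. An F-test covered any difference among the groups. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The comparison of day 14 with day 7 also tests whether the changes from control differ between the stages. Before the data were examined, 34 gene lists with 798 genes were fixed, of which 721 had a named probe set and 657 were tested; the design, the alternatives and the rule for naming genes were fixed then too. Of the lists, 33 were tested with camera against all other genes, with the correlation between genes preset at 0.01 and again with the correlation estimated from the data, and adjusted over the lists within a comparison. Of the 40 calls with the preset correlation, 13 at day 7, 15 at day 14 and 12 between the days, 0 held with the estimated correlation, where the lowest adjusted p was 0.36, 0.21 and 0.30. A list's median, mean and camera direction differed in sign for 8, 10 and 8 lists in the 3 comparisons, and 0 of those were called.

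Named genes were, per comparison, the 12 largest positive and 12 largest negative changes among called genes whose groups did not overlap, without predicted genes and clones, up to 4 called members per direction of each list (with none called, at most 2 with the smallest p), and 17 genes set in advance, which include Egr1, Egr2, Egr3, Cdkn1a, Ccnd1, Mki67, Kit, Flt3 and Cd48. Ly6a, which was among the 17, had no probe set with its symbol alone and is not analysed here, and 1 other of the 17 is not reported here. The list of sex-linked genes was described but not tested.

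Alternatives were quantile normalization, arrays set to the same 75th percentile, no floor, an offset of 32 without floor, no filter or a stricter filter (60th percentile) on dim probe sets, the mean of a gene's probe sets, every probe set on its own, the replicate number as a block, only the 2 groups compared, a trended robust variance prior, array weights, a change of at least 2-fold, and leaving out each array in turn. The count of list members with each array left out was added after seeing the data. A planned test of the 3' to 5' signal of the Affymetrix control probe sets was not run, since 0 such probe sets were in the table used here. The steps were tested on simulated data with the real means and spreads of the 12652 genes and 200 genes changed by known amounts. In the real data 6626 genes were called for day 14 against control and 6455 for day 14 against day 7. The adjusted threshold depends on how many genes change, so recovery in those comparisons can differ from the simulated values. At log2 changes of 0.25, 0.5 and 1, 17.9%, 76.1% and 93.9% were recovered for day 7 against control (7 of 132 calls false), 10.4%, 76.1% and 97.0% for day 14 against control (8 of 130 false), and 11.9%, 71.6% and 95.5% for day 14 against day 7 (7 of 126 false). Unchanged simulated lists gave 1 call in 990 camera tests with the preset correlation, but genes were simulated as independent, so this does not test that setting on correlated genes. Figures were drawn with matplotlib 3.10.9.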

Results

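RNA of sorted bone marrow cells was profiled on 9 mouse Affymetrix 430 2.0 arrays, which measure transcripts as probe set intensities. The cells were CD45.1+ LKS+ cells, a fraction that lacks lineage markers, carries Kit and Sca-1 and holds blood stem cells and early progenitors; CD45.1 is a variant of a surface antigen of blood cells that lets cells of one origin be told from others. Samples fell into 3 groups with 3 replicates each: control mice, mice at day 7 of leukemia and mice at day 14 of leukemia. The question the series poses is how gene expression of normal stem and progenitor cells differs across stages of acute myeloid leukemia. The controls carry no time label, so time and leukemia cannot be separated in the comparisons with control. Neither leukemic day has controls labelled for it, so elapsed time and stage cannot be separated between day 14 and day 7 either. The labels call the replicates biological, but nothing says whether each came from a separate animal or sort, so p-values measure only the spread between these samples. The number of arrays limits the precision, and no batch label was given. The median intensity per array ran from 23.4 to 24.2, and 12652 genes with signal were tested.

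The day 14 arrays stood apart from all others. Across the genes tested, the Pearson correlation between arrays of the same group was 0.994 to 0.997, that between control and day 7 arrays 0.990 to 0.995, and that between control and day 14 arrays 0.965 to 0.981. These correlations are across genes, which are not independent replicates. A principal component with 69.6% of the variance separated the 3 day 14 arrays from the other 6, and the next, with 12.3%, separated control from day 7. The median replicate SD of log2 intensity was 0.09 in control, 0.07 at day 7 and 0.10 at day 14 (n = 3 each). With limma and Benjamini-Hochberg adjustment, 6937 of the 12652 genes differed among the 3 groups.

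At day 7, genes of mitosis were higher and genes of the type I interferon response were lower than in control. Ube2c, which tags mitotic proteins for degradation, had an intensity of 391 ± 76 in control and 957 ± 85.2 at day 7 (SD, n = 3), a 2.47-fold rise. Mki67, a marker of cycling cells, went from 1076 ± 213 to 1710 ± 199. Ifit1, an antiviral gene switched on by interferon, fell from 376 ± 56.7 to 168 ± 44.1. The orphan nuclear receptor gene Nr4a3 rose 3.14-fold, from 36.6 ± 1.44 to 115 ± 16.6, and the transcription factor gene Egr3 rose 2.92-fold. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 1.61-fold. Many calls rested on the filter or on single arrays: of 60 named genes called at day 7, 52 lost their call without the filter on dim probe sets, 35 lost their call without control replicate 3, 33 without day 7 replicate 2, 32 without day 7 replicate 3, 21 without control replicate 1 and 21 without day 7 replicate 1.

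Of 35 measured G2/M and mitosis genes, 32 rose at day 7, none fell and 3 did not pass, with a median log2 change of 0.78; adjusted over the list alone, 35 rose. Birc5 and Nusap1, genes of chromosome segregation, each rose by 1.13 (SE 0.14 and 0.15). The list test camera gave an adjusted p of 4.4e-33 with a preset correlation, and adjusted p = 0.36 with an estimated correlation. The count of members past the threshold was 14 without control replicate 1, 10 without control replicate 3, 12 without day 7 replicate 1 and 10 without day 7 replicate 2. Of 32 DNA replication and G1/S genes, only Dbf4, which activates replication origins with Cdc7, rose (log2 change 0.49, SE 0.08); 4 rose adjusted over the list alone, and without control replicate 2 the count over all genes was 6, without control replicate 3 it was 0. The list had a median of 0.21 and a camera adjusted p of 0.00025 (adjusted p = 0.61 with an estimated correlation). Among 9 CDK inhibitors and pocket proteins, Cdkn3 (0.93), Cdkn2c (0.81), Cdkn1a (0.69) and Cdkn2d (0.29) rose, with 4 also adjusted over the list alone and a camera adjusted p of 0.026 (adjusted p = 0.36 with an estimated correlation), which was 0.11 without the filter on dim probe sets, 0.059 with only the 2 groups compared and 0.11 with array weights. Cdkn2d lost its call with either other scaling. The 4 became 2 or 3 with any single array left out, and 2 without day 7 replicate 1 or day 7 replicate 3. Cdkn1b, at -0.16, and Cdkn1c, at -0.06, did not pass (adjusted p 0.24 and 0.80). Of 14 G1 cyclins and CDKs, E2f2 rose by 0.67 and 13 did not pass, and E2f2 lost its call without control replicate 1, control replicate 3 or any day 7 replicate; adjusted over the list alone, 2 rose and 3 fell, and the camera adjusted p was 0.80.

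Of 31 type I interferon-response genes, 14 fell at day 7, none rose and 17 did not pass; adjusted over the list alone, 27 fell. The list's median log2 change was -0.67. The log2 change was -1.34 (SE 0.27) for Ifit3, -1.05 (SE 0.23) for Usp18, a brake on interferon signalling, and -0.98 (SE 0.22) for Irf7, a transcription factor of the response. By camera the adjusted p was 6.9e-23, and adjusted p = 0.36 with an estimated correlation. The 14 became 2 without control replicate 1, and 1 without control replicate 3, without day 7 replicate 2 or without day 7 replicate 3. Of 27 interferon-gamma and antigen presentation genes, 6 fell, among them the GTPase genes Iigp1 (-1.33), Gbp6 (-1.20) and Irgm2 (-1.02), and Cxcl9, below the 40th percentile in 2 of 3 control arrays, rose by 0.77; adjusted over the list alone, 9 fell and 1 rose. Their camera adjusted p was 4.0e-06 (adjusted p = 0.42 with an estimated correlation). Control replicate 1 lay at 0.28 for this list, the mean of its genes relative to all controls, against -0.15 and -0.14 in the other controls, so the fall is smaller without it. The count of 6 and 1 became 2 in all without control replicate 3, day 7 replicate 2 or day 7 replicate 3, and 4 without day 7 replicate 1 or day 14 replicate 3.

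A few immediate-early genes, which respond within minutes to signals, rose at day 7. Of 30 measured EGR and immediate-early genes, 5 rose and 25 did not pass, with 7 adjusted over the list alone; the 5 included Nr4a3 (1.65, SE 0.13), Egr3 (1.55, SE 0.28), Maff (0.96, SE 0.11) and Egr1 (0.29, SE 0.07), whose call was lost with either other scaling. Camera gave the list an adjusted p of 0.0015 (adjusted p = 0.58 with an estimated correlation), which became 0.38 without control replicate 2 and 0.13 with array weights. The list's count was 2 without control replicate 3 and 3 without any of the day 7 replicates. Egr3 and Nr4a3 each rest on a probe set from which another of the same gene departed: the other Egr3 probe set changed by 0.09 and the other bright Nr4a3 probe set by 0.23. In the NOTCH list of 19 genes, the target genes Hes1 (1.13), Hey1 (1.09) and Nrarp (0.37) rose and 16 members did not pass (4 rose adjusted over the list alone; camera adjusted p 0.24). Nrarp lost its call with either other scaling, and the 3 became 1 without control replicate 3, day 7 replicate 2 or day 7 replicate 3. Of 18 myeloid progenitor and granule genes, Elane, which encodes neutrophil elastase, rose by 1.40 and Ms4a3 by 1.16 (2 rose and 1 fell adjusted over the list alone; camera adjusted p 0.12). Neither passed without control replicate 3, and 1 of them without day 7 replicate 1; camera's adjusted p was 0.0099 and 0.0089 in the direction up without control replicate 3 and without day 7 replicate 2.

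The strongest rises at day 7 by fold were in antibody genes. Jchain, the joining chain of secreted antibodies, rose from 11.2 ± 8.90 to 96.5 ± 6.94, Igkv8-30 rose 6.48-fold and Igkv15-103 at least 3.31-fold, since its control signal lay below the 40th percentile of every control array. Jchain lay below that percentile in 2 of 3 control arrays and Igkv8-30 in 1 of 3, so their folds are uncertain, and the Igkv8-30 probe set carries a suffix for probes that can also bind other transcripts. Of 11 measured B cell genes, the pre-B receptor genes Vpreb1 (1.09) and Igll1 (0.87) rose and 9 did not pass; 6 rose adjusted over the list alone, and the camera adjusted p was 0.0074 (adjusted p = 0.36 with an estimated correlation), 0.054 without control replicate 2 and 0.16 with the stricter filter on dim probe sets. The 2 became 1 without control replicate 1 or control replicate 3, and 0 without day 7 replicate 2 or day 7 replicate 3. Of 14 T and NK cell genes, Cd28 (1.45) and Bcl11b (0.85) rose and 12 did not pass; 4 rose adjusted over the list alone, and the camera adjusted p was 0.014 (adjusted p = 0.36 with an estimated correlation), 0.077 without control replicate 2, 0.15 with the stricter filter on dim probe sets and 0.19 with array weights. The 2 became 4 without control replicate 2 or day 14 replicate 3. Of 26 measured HSC-enriched genes none passed with limma at day 7. Only 3.34% of all tested genes were called then, so this does not show that the list was stable. In the list 8 had an unadjusted p below 0.05 and 4 fell adjusted over the list alone. The median was -0.08, where the median absolute change of all tested genes was 0.09. Camera gave an adjusted p of 0.00050 in the direction down (adjusted p = 0.42 with an estimated correlation). The 2 smallest p in that list belonged to Mycn, at -0.60, and Fgd5, at -0.32.

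In all, 423 of 12652 genes passed at day 7 with limma and Benjamini-Hochberg adjustment, 280 higher and 143 lower, and 44 of them by at least 2-fold. Without adjustment 2511 genes had a p below 0.05, and in 26.53% of genes the groups did not overlap, where 10% is the chance for a single gene. Genes move together, so the share without any change can lie away from 10%, and its spread was not measured. The count fell to 59 without the filter on dim probe sets, to 187 without control replicate 1, 79 without control replicate 3, 137 without day 7 replicate 1, 84 without day 7 replicate 2 and 122 without day 7 replicate 3. Of the 24 genes with the largest changes, the calls for Cd28, Coq10b, Igkv8-30, Nr4a3 and Ube2c were kept in every alternative run for them, arrays left out included; a 2-fold change and every probe set on its own were not among these.

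At day 14 the cell cycle genes lay below control. Cdk1, the kinase that drives entry into mitosis, fell from 342 ± 68.6 in control to 130 ± 16.5 (SD, n = 3), the replication licensing gene Cdc6 from 364 ± 48.2 to 120 ± 26.5, and the G1 cyclin gene Ccnd1 from 275 ± 26.8 to 104 ± 15.4. The immediate-early gene Egr3 went from 40.6 ± 19.7 to 626 ± 162, a 16.1-fold rise, and the NOTCH target gene Hey1 from 29.95 ± 1.78 to 243 ± 44.6. Cdkn1a rose 2.37-fold to 1851 ± 193, and the platelet factor gene Pf4 rose 4.36-fold, from 144 ± 22.7 to 624 ± 49.5. Ifit1 fell further, to 75.5 ± 17.3.

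**Figure D1:**
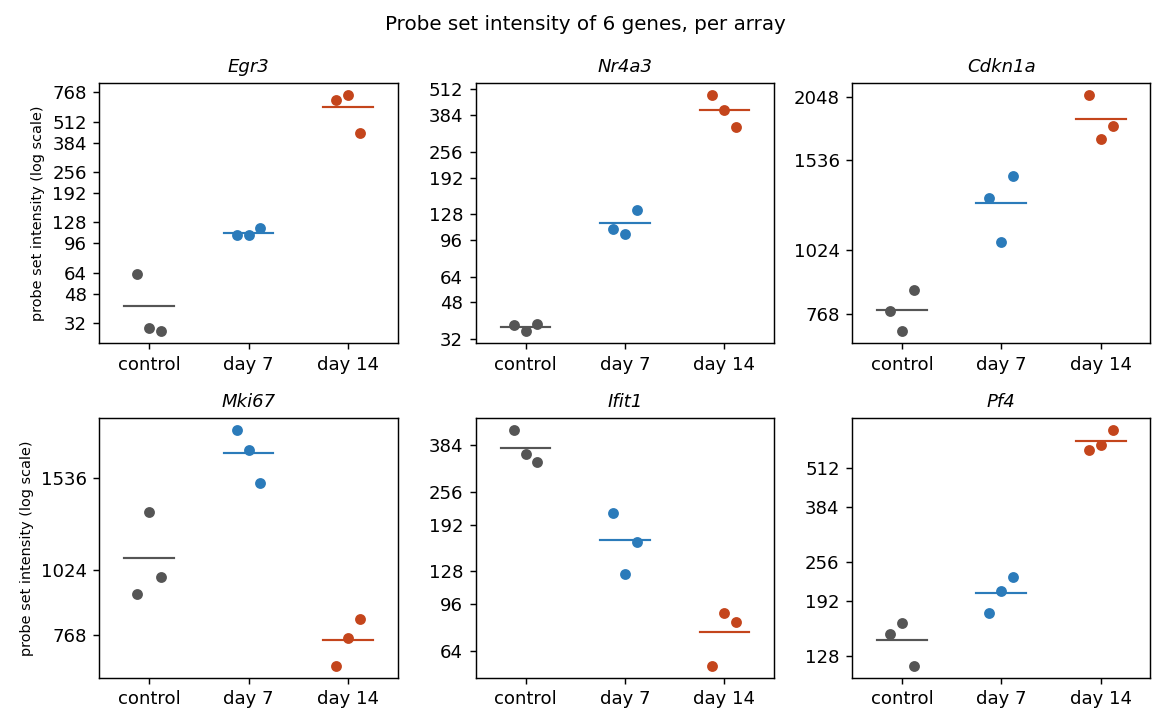
Probe set intensity (log scale, y axis) of 6 genes in each array of the control, day 7 and day 14 groups (x axis); points are arrays, 3 per group, and lines are group means. Mki67 was higher at day 7 (mean 1710) and lower at day 14 (mean 750) than in control (mean 1076), while Egr3, Nr4a3, Cdkn1a and Pf4 were higher at day 14 than in control and Ifit1 was lower.

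Of 35 G2/M and mitosis genes, 33 fell at day 14, none rose and 2 did not pass (33 fell adjusted over the list alone), with a median log2 change of -0.79. Nuf2 (-1.32, SE 0.21), Kif20a (-1.26, SE 0.16) and Mki67 (-0.51, SE 0.14) fell. Camera gave the list an adjusted p of 2.8e-07, and adjusted p = 0.51 with an estimated correlation. Of 32 DNA replication and G1/S genes, 31 fell, the same number as adjusted over the list alone, and Dbf4 alone rose (0.32). Their median was -0.96, with Ccne2 at -1.57, Tk1 at -1.51 and Rrm2 at -1.42; the camera adjusted p was 5.7e-10 (adjusted p = 0.48 with an estimated correlation). Of 14 G1 cyclins and CDKs, 10 fell, among them Ccnd1 (-1.41, SE 0.11) and E2f1 (-0.96, SE 0.14), Cdk6 rose by 0.28, and 3 did not pass; adjusted over the list alone 12 fell. Their camera adjusted p was 0.0025 (adjusted p = 0.48 with an estimated correlation). The 9 CDK inhibitors and pocket proteins went both ways: Cdkn1a (1.25), Cdkn2d (0.85) and Rb1 (0.68) rose, Rbl1 (-1.26), Cdkn3 (-0.54) and Cdkn2c (-0.38) fell, and 3 did not pass, for a camera adjusted p of 0.61 (3 rose and 4 fell adjusted over the list alone). The call for Cdkn2c was lost with both other scalings. Cdkn1b, at -0.03, and Cdkn1c, at -0.13, had adjusted p of 0.70 and 0.31 in limma, and both values lay above 0 with quantile normalization.

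The EGR and immediate-early list had 26 risers among 30 genes, none that fell and 4 that did not pass, with a median of 0.65; adjusted over the list alone, 26 rose and 1 fell. Nr4a3 rose by 3.46 (SE 0.13), Maff by 2.47 (SE 0.11), Klf4 by 2.13 (SE 0.21), Egr2 by 1.36 (SE 0.25) and Egr1 by 0.67 (SE 0.07). In camera the adjusted p was 1.6e-11, and adjusted p = 0.33 with an estimated correlation. Fos, singled out after its values were seen, was at -0.15 among the 4 that did not pass and had an intensity of 8414 ± 715 already in control. The other Egr3 probe set changed by 0.27 at day 14, against 4.01 for the brighter probe set used, and the other bright Nr4a3 probe set by 0.37. Of 23 TNF and NF-kB-response genes, 17 rose and Tnf itself fell by 0.42 (17 and 1 adjusted over the list alone); Cxcl2 (2.29), Cd83 (1.88) and Tnfaip3 (1.51) rose. Their camera adjusted p was 1.1e-07 (adjusted p = 0.33 with an estimated correlation), and the call for Tnf was lost with both other scalings. Of 22 TGF-beta and BMP-response genes, 14 rose, led by Skil (2.52, SE 0.11) and Smad7 (1.47, SE 0.12), brakes on TGF-beta signalling, and 3 fell, among them Tgfbi (-0.92); adjusted over the list alone 15 rose and 3 fell. Camera gave an adjusted p of 2.0e-05 (adjusted p = 0.21 with an estimated correlation). In the NOTCH list of 19, 8 rose, with Hey1 at 3.01, Hes1 at 2.60 and Nrarp at 0.75, and Lfng fell by 0.35 (8 and 1 adjusted over the list alone); the camera adjusted p was 0.00077 (adjusted p = 0.26 with an estimated correlation).

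Interferon-response genes stayed low. Of 31 type I members, 29 fell at day 14, none rose and 2 did not pass (30 fell adjusted over the list alone), with a median of -0.92; Ifit3 (-2.11, SE 0.27), Usp18 (-1.84, SE 0.23) and Rtp4 (-1.71, SE 0.17) fell. For this list camera's adjusted p was 3.0e-08, and adjusted p = 0.51 with an estimated correlation. Of 27 interferon-gamma and antigen presentation genes, 11 fell, with Irgm2 at -1.87 and Igtp at -1.28, and the adhesion gene Icam1 rose by 0.39 (11 and 1 adjusted over the list alone; camera adjusted p 0.23); this fall, too, is smaller without control replicate 1.

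Genes of several blood lineages rose in the sorted cells at day 14. Of 19 megakaryocyte and platelet genes, 15 rose, none fell and 4 did not pass (15 adjusted over the list alone), with a median of 1.04. Pf4 rose by 2.12 (SE 0.13), Gp1bb by 1.73 (SE 0.08) and Itgb3 by 1.68 (SE 0.11), while Ppbp, another abundant platelet gene singled out after its values were seen, measured 18.3, 103 and 17.6 in the 3 day 14 arrays against 22.6 ± 4.06 in control. The list's camera adjusted p was 5.2e-11, and adjusted p = 0.21 with an estimated correlation. Of 18 myeloid progenitor and granule genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone); Elane (1.80), Igsf6 (1.61) and Fcgr3 (1.41) rose, and Gfi1, a repressor that restrains stem cell cycling, fell by 0.88. Their camera adjusted p was 0.0040 (adjusted p = 0.51 with an estimated correlation). Of 16 mature neutrophil and monocyte genes, 6 rose, such as Cybb (1.82) and Cd14 (1.42), and 3 fell, among them S100a8 (-0.99) and Anxa1 (-0.86), with the same counts adjusted over the list alone and a camera adjusted p of 0.19. Of 26 HSC-enriched genes, 5 rose, with Vwf at 1.30 and Tek at 0.47, 4 fell, with Hoxb4 at -0.50 and Fgd5 at -0.40, and 17 did not pass (5 and 4 adjusted over the list alone, camera adjusted p 0.36). Among the 4 that fell, Procr lost its call with arrays set to the same 75th percentile and Ndn with both other scalings. Kit, at -0.03, Cd34, at -0.09, Flt3, at -0.08, and Slamf1, at -0.0026, did not pass, and all 4 values were above 0 with arrays set to the same 75th percentile. The progenitor marker gene Cd48 fell by 0.85.

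**Figure D2:**
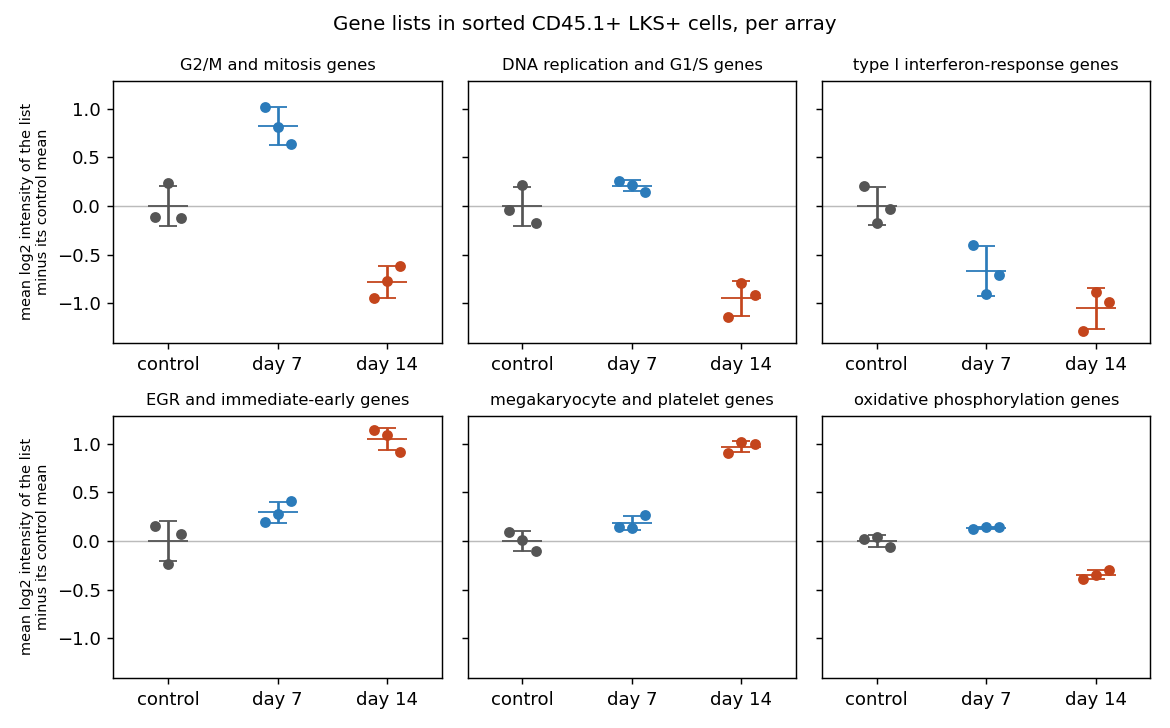
Mean log2 intensity of 6 gene lists per array minus the list's control mean (y axis) in the control, day 7 and day 14 groups (x axis); points are arrays, horizontal marks the mean and bars the SD over 3 arrays. The G2/M and mitosis list lay at 0.82 at day 7 and -0.78 at day 14, and the EGR and immediate-early list at 0.30 and 1.05.

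Many oxidative phosphorylation genes were lower at day 14: 36 of 45 fell, none rose and 9 did not pass (36 adjusted over the list alone), with a median of -0.33. Ndufa5, a subunit of complex I (-1.11, SE 0.11), and Ndufa4 (-0.88, SE 0.07) fell. The camera adjusted p was 2.8e-07 (adjusted p = 0.48 with an estimated correlation). At day 7 the same list had 3 that rose, Uqcrfs1 (0.30), Cox8a (0.30) and Ndufa2 (0.26), with 13 adjusted over the list alone and a camera adjusted p of 2.0e-07 in the direction up (adjusted p = 0.42 with an estimated correlation). Ndufa2 lost its call with either other scaling and the other 2 with arrays set to the same 75th percentile, and none of the 3 passed without control replicate 1, control replicate 3, any day 7 replicate, day 14 replicate 2 or day 14 replicate 3.

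In all, 6626 of 12652 genes, or 52.37%, passed at day 14 with limma and Benjamini-Hochberg adjustment, and 411 of them changed by at least 2-fold, 186 higher and 225 lower. The groups did not overlap in 58.13% of genes, where 10% is the chance for a single gene. Of the calls, 2314 were higher and 4312 lower, a higher share of 34.9%. That split moved with the scaling, to 2788 higher and 3389 lower with quantile normalization and to 3953 higher and 2929 lower (57.4%) with arrays set to the same 75th percentile. The latter moved the median change of all tested genes from -0.06 to 0.06. The filter on dim probe sets mattered too. With the stricter filter the higher share was 28.2% and the median change -0.128, and without a filter they were 36.8% and 0. Small changes are to be read against these shifts.

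The comparison of day 14 with day 7 tests whether the changes from control differ between the stages. All 35 G2/M and mitosis genes were lower at day 14 than at day 7 (35 adjusted over the list alone), with a median log2 difference of -1.67; Ube2c (-2.15, SE 0.14), Kif20a (-2.07, SE 0.16) and Cdk1 (-2.04, SE 0.14) fell. The camera adjusted p was 2.0e-15 (adjusted p = 0.34 with an estimated correlation). Of 32 DNA replication and G1/S genes, 31 fell (31 adjusted over the list alone), Tk1 the most at -2.21 (SE 0.18), with a camera adjusted p of 3.0e-12 (adjusted p = 0.34 with an estimated correlation). Among 14 G1 cyclins and CDKs, 10 fell and 1 rose (camera adjusted p 0.011, and adjusted p = 0.47 with an estimated correlation). Gzmb, which encodes the cytotoxic protease granzyme B, rose 6.31-fold from 63.5 ± 12.2 at day 7 to 400 ± 63.9 at day 14, and Egr3 rose 5.52-fold. Of 30 EGR and immediate-early genes, 22 rose and none fell (22 and 0 adjusted over the list alone; camera adjusted p 3.3e-10, and adjusted p = 0.34 with an estimated correlation), and of 19 megakaryocyte and platelet genes 15 rose (15 adjusted over the list alone; camera adjusted p 1.3e-09, and adjusted p = 0.30 with an estimated correlation). Skil rose by 1.94, Klf4 by 1.78 and Cdkn1a by 0.56. Among 23 TNF and NF-kB-response genes, 17 rose and 1 fell (camera adjusted p 1.9e-06, and adjusted p = 0.34 with an estimated correlation). For 22 TGF-beta and BMP-response genes these were 12 and 2 (camera adjusted p 6.3e-05, and adjusted p = 0.30 with an estimated correlation). For 19 NOTCH genes they were 7 and 2 (camera adjusted p 0.0039, and adjusted p = 0.34 with an estimated correlation). The type I interferon list had 15 of 31 members lower (15 adjusted over the list alone), Ifit1 at -1.15 among them, and a camera adjusted p of 0.077, which was 0.026 with arrays set to the same 75th percentile, 0.031 without the filter on dim probe sets, 0.0047 without day 7 replicate 2 and 0.019 without day 14 replicate 2; its count was 7 without day 7 replicate 1 and 7 without day 14 replicate 1. The oxidative phosphorylation list had 41 of 45 lower (42 fell and 1 rose adjusted over the list alone, camera adjusted p 8.6e-11, and adjusted p = 0.34 with an estimated correlation). Among 26 HSC-enriched genes, 7 rose and 0 fell (camera adjusted p 0.0088, and adjusted p = 0.47 with an estimated correlation). In the stromal and endothelial list of 12, 7 rose and 1 fell (camera adjusted p 0.0081, and 0.34 with an estimated correlation). In the T and NK cell list of 14, 8 rose and 2 fell (camera adjusted p 0.013, and 0.34 with an estimated correlation). Its adjusted p was 0.065 with arrays set to the same 75th percentile and 0.060 without the filter on dim probe sets.

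In all, 6455 of 12652 genes, or 51.02%, differed between day 14 and day 7 with limma and Benjamini-Hochberg adjustment. Of these, 2204 were higher and 4251 lower, and 446 differed by at least 2-fold. Counts of list members in this comparison are to be read against those shares. The groups did not overlap in 60.29% of genes, where 10% is the chance for a single gene. The higher share of calls was 34.1%, 44.0% with quantile normalization (2697 higher, 3434 lower) and 57.8% with arrays set to the same 75th percentile (4029 higher, 2942 lower).

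**Figure D3:**
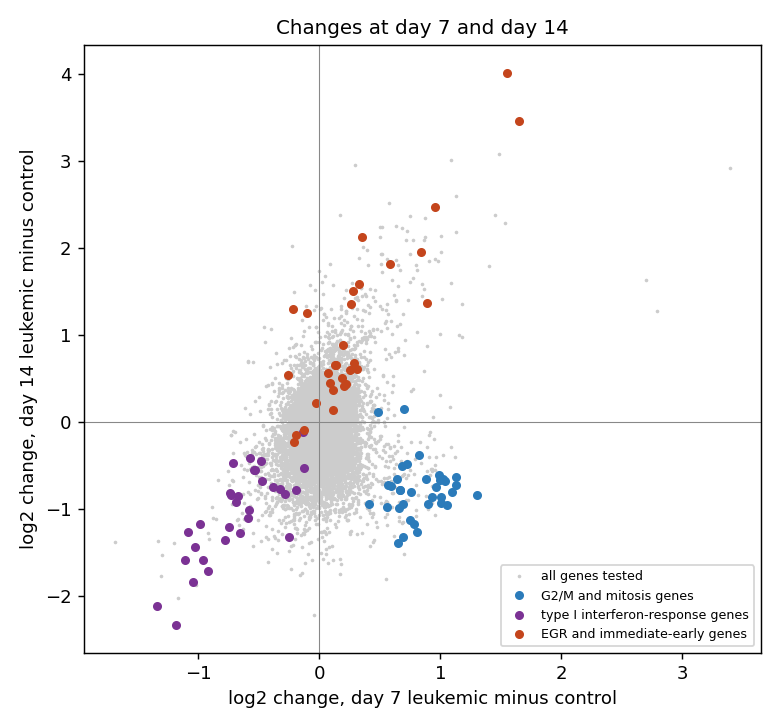
Log2 change against control at day 7 (x axis) and at day 14 (y axis) of each of the 12652 genes tested; colours mark 3 gene lists. G2/M and mitosis genes lay above 0 at day 7 and mostly below 0 at day 14, while type I interferon-response genes lay below 0 at both.

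Across genes, the day 7 and day 14 changes correlated with Pearson r = 0.255, and 54.89% had the same sign. Both comparisons use the same control arrays. A simulation of unchanged groups that share simulated controls gave r = 0.499 and 66.63%, as the mean of 100 draws. That simulation held no true changes, so its r and share of signs are no baseline for the observed ones. The covariance of the log2 changes was 0.0215, against 0.00475 in the simulation, a difference of 0.0167. Of the genes called at both days, 111 were higher at both, such as Nr4a3, Egr3, Hey1 and Jchain, against 51.2 for independent lists, and 118 were lower at both, such as Ifit1 and Usp18, against 48.7. In the opposite directions, 116 were higher at day 7 and lower at day 14, Mki67 and Cdkn3 among them, against 95.4 for independent lists, and 8 were lower at day 7 and higher at day 14, against 26.2. With 3 controls, no split keeps 2 arrays in each part, so part of the excess in the same direction may come from the shared controls.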

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

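All tests of explanations in this part, the splits of the arrays included, were chosen after the results were seen; the comparison of day 14 with day 7 was planned.

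The changes from control differed between the stages, by the test of day 14 against day 7, in 6455 genes, and 124 genes were called in opposite directions at the 2 days. The median difference was -1.67 for the G2/M and mitosis list, -1.12 for the DNA replication and G1/S list and -0.48 for the oxidative phosphorylation list. Single mitosis genes differed by -2.15 (Ube2c), -2.07 (Kif20a), -2.04 (Cdk1), -2.02 (Spc25), -2.00 (Cenpf), -1.96 (Ttk), -1.93 (Plk1) and -1.19 (Mki67). Mitosis genes stood above G1/S genes at day 7: the mean of the mitosis list minus that of the G1/S list, relative to control, was 0.76, 0.60 and 0.49 in the 3 day 7 arrays, 0.19, 0.02 and 0.30 in the day 14 arrays and -0.07, 0.02 and 0.05 in the controls.

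More than 1 in 2 of the tested genes differed between day 14 and control, and the tables argue against scaling as the whole cause: after quantile normalization, which gives every array the same distribution, 6177 genes were called against 6626. Of 100 splits of the 9 arrays, the true grouping included, only the true grouping gave as many genes differing among the 3 groups (6937, against 5646 in the next). This split test was run after the day 14 arrays were seen to stand apart. It also assumes independent replicates and no shared batch, which the labels do not give, so no conclusion about chance is drawn from it. For the pairs of groups, 1 of 10 splits gave as many genes each time, with 423, 6626 and 6455 against 0 in any other, but 10 splits are too few for a share under 0.05. The labels named 0 array batches, so a batch shared by the day 14 arrays cannot be told apart from the stage. The stage of leukemia stays open as a biological explanation, and so does the time between control and leukemic samples, which the labels leave unstated.

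Immediate-early genes rose at day 14. With the mean of each gene's probe sets the list's median was 0.63, with a camera adjusted p of 1.6e-11 (0.65 and 1.6e-11 with the brightest). That mean still holds the brightest probe set, and genes with 1 probe set keep their value, so it cannot decide whether the choice of probe set matters. Egr3 and Nr4a3 each have a probe set that moved far less. Handling of the cells before lysis may induce immediate-early genes. Most genes of a handling set belong to the list itself, so their changes decide nothing: Atf3 (1.58), Junb (0.65), Ier2 (0.60), Zfp36 (0.41) and Jun (0.37) rose, and Dusp1 (-0.09) and Fos (-0.15) did not pass. The 2 outside it, Hspa1a (0.07) and Hspa1b (0.27), had a median log2 change of 0.17 and did not pass, and 2 genes are too few to decide, so handling and stage cannot be told apart.

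Genes of platelets and myeloid cells rose at day 14, and other cells in the sort could bring such transcripts, although the gate removes lineage-positive cells. The platelet genes Ppbp, Tubb1, Gp9, Nrgn, Gp5, Treml1, Gp1bb and Clec1b had a median change of 0.43 with a spread of 0.59, against 1.04 for the megakaryocyte and platelet list; Gp1bb rose by 1.73, and Ppbp measured 103 in 1 of 3 day 14 arrays and near its control signal in the others. The neutrophil genes S100a8, S100a9, Camp, Ngp and Ltf had a median change of -0.24 with a spread of 0.52, against 0.51 for the myeloid progenitor and granule list. These spreads are SDs across genes, not errors of the medians, and all the platelet genes named belong to the list they were set against. The values therefore decide neither for nor against platelets or mature neutrophils, so other cells in the sort and the stage cannot be told apart. Cells primed for the megakaryocyte or myeloid lineage within the gate, and a change within the stem cells themselves, stay open and were not tested.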

How the results depend on the processing

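The counts of list members with single arrays left out were added after seeing the data; all other alternatives were planned. At day 7, where 423 genes were called, the count was 44 at a change of at least 2-fold, 59 without the filter on dim probe sets (which tests more genes), 280 with the replicate block, 674 with a trended robust prior, 703 with an offset of 32, 938 over every probe set and 2181 with array weights, which set control replicate 1 at 3.25 and day 7 replicate 2 at 3.60. Leaving out 1 array gave 79 to 555. At day 14 (6626 called) the count was 411 at a change of at least 2-fold and 12290 over every probe set; between the days (6455) these were 446 and 11673, and among the 3 groups (6937) 425 and 13125. The correlation of the day 7 and day 14 changes (0.255) was 0.208 with an offset of 32, 0.1997 with array weights and 0.1995 to 0.328 with 1 array left out. Replicate numbers did not pair the arrays: 1 of 9 pairs had deviations correlated above 0.1 (range -0.193 to 0.12). In 2 of the 9 pairs the best match in the other group bore the same number. With the replicate block the other counts were 6333, 6257 and 6635. Of 9936 results for named genes under alternatives, 570 lost the call, 60 gained it and 6 reversed, each with the mean of a gene's probe sets: at day 14 Satb1 (-0.107), Cflar (0.0106) and Pdia6 (0.0746), and between the days Meis1 (-0.016), Notch4 (0.0333) and Pdia6 (0.0122); the cause was not tested. Of 2079 list results, 69 lost the call, 40 of them with an estimated correlation, 47 gained it and 0 reversed. Of named calls, 7 of 60 at day 7, 159 of 202 at day 14 and 163 of 190 between the days were kept in every alternative run for them, which leaves out the 2-fold change and every probe set, and for dim genes the stricter filter. The 3' to 5' alternative was not run. Only genes below the 40th percentile in every array of a group have bounds; those below it in some arrays, such as Cd83, Egr2 and S100a8, have plain values, which are less certain.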

Other observations

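The lists and genes below were fixed in advance unless said otherwise. Leaving out single arrays when counting list members was added after seeing the data. At day 14, 52.37% of the 12652 tested genes were called, 2314 higher and 4312 lower. A count of members called in either direction that is near or below that share is not by itself particular to its list. Counts in a single direction are to be read against the calls in that direction over all genes, a split that moved with the scaling.

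In the following lists of the stress response and of metabolism, genes were called in both directions at day 14, unlike in the oxidative phosphorylation list given above. Of 24 heat shock and unfolded protein genes, 10 rose, led by Ddit3 (log2 change 1.66, SE 0.12) and Atf4 (0.91, SE 0.06), transcription factors of the integrated stress response, and 5 fell, among them the chaperone genes Hsph1 (-0.74) and Hspd1 (-0.45); the counts adjusted over the list alone were the same. Ddit3 had an intensity of 176 ± 32.3 in control, 299 ± 27.0 at day 7 and 552 ± 8.78 at day 14 (SD, n = 3). The camera adjusted p was 0.016 (adjusted p = 0.33 with an estimated correlation), 0.068 after quantile normalization, 0.051 with arrays set to the same 75th percentile and 0.064 without the filter on dim probe sets. At day 7, Ddit3 (0.77) and Atf4 (0.38) rose, 4 adjusted over the list alone, with a camera adjusted p of 0.026 (adjusted p = 0.36 with an estimated correlation), or 0.077 without control replicate 2; the 2 became 1 without control replicate 3, day 7 replicate 2 or day 7 replicate 3. Of 24 hypoxia and glycolysis genes, 6 rose and 9 fell at day 14 (6 and 10 adjusted over the list alone; camera adjusted p 0.72): Vegfa rose 4.59-fold and the glucose transporter gene Slc2a1 by 0.69, while the glycolysis genes Tpi1 (-0.63) and Pgam1 (-0.60) fell. Of 15 cholesterol synthesis genes, 4 rose, with Insig1 at 0.92, and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p 0.52), and the 7 became 3 without control replicate 3 or day 14 replicate 2 and 4 without day 14 replicate 1. The 3 that fell, Mvd, Dhcr7 and Sqle, all lost their calls with both other scalings. At day 7 the same list had Msmo1 alone called, at -0.46 (1 adjusted over the list alone), with a camera adjusted p of 0.012 in the direction down (adjusted p = 0.36 with an estimated correlation), 0.051 with the mean of a gene's probe sets and 0.054 without day 7 replicate 1. Msmo1 did not pass without any control replicate, any day 7 replicate or day 14 replicate 3. Of 20 antioxidant genes, 4 rose and 6 fell, with Gsr at 0.42 and Prdx4 at -0.65 (4 and 6 adjusted over the list alone, camera adjusted p 0.78). Nqo1, among the 6, lost its call with both other scalings. The 34 cytosolic ribosomal protein genes had a median of 0.01, with Rpl37 at 0.21 and Rpl12 at -0.43 among the 3 called (0 and 1 adjusted over the list alone); their camera adjusted p was 0.37, and 0.031 with arrays set to the same 75th percentile.

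Lymphoid and other lineage genes moved apart at day 14. Of 14 T and NK cell genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone), with Gzmb at 2.95, the costimulatory receptor gene Cd28 at 2.38, Bcl11b at 1.59 and Nkg7 at -0.49; the camera adjusted p was 0.0012 (adjusted p = 0.26 with an estimated correlation). Of 11 B cell genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p 0.11): Igll1 rose by 1.53 and Ebf1, a factor of B cell commitment, was at least 2.06-fold higher, while Bank1 (-1.16) and Cd79b (-0.58) fell. Of 18 lymphoid-primed progenitor genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone, camera adjusted p 0.37). Rag1 was among the 2 that rose, while Rag2, at least 1.85-fold lower, was among the 6 that fell. Rag1 lay below the percentile of the filter on dim probe sets in 1 control array, so the size of its rise is less certain. Of 7 mast cell and basophil genes, 3 rose, Cpa3 at 1.14 among them (3 adjusted over the list alone; camera adjusted p 0.028, and adjusted p = 0.36 with an estimated correlation), and the list's adjusted p was 0.051 with arrays set to the same 75th percentile, 0.064 without the filter on dim probe sets and 0.066 with array weights. Of 12 stromal and endothelial genes, 5 rose and Emcn fell by 0.69 (5 and 1 adjusted over the list alone); Pdgfrb was at 0.89 and Kdr at 0.69. Their camera adjusted p was 0.034 (adjusted p = 0.33 with an estimated correlation), 0.093 after quantile normalization, 0.081 with arrays set to the same 75th percentile, 0.056 without the filter on dim probe sets, 0.066 with the mean of a gene's probe sets, 0.066 with array weights, 0.051 without control replicate 2 and 0.052 without control replicate 3. Of 19 macrophage and dendritic cell genes, 2 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p 0.78), and the 5 became 3 without day 14 replicate 1. Megakaryocyte and platelet genes at day 7 had 1 riser, Gp1bb (0.52), with 3 adjusted over the list alone and a camera adjusted p of 0.0074 (adjusted p = 0.42 with an estimated correlation); the list's adjusted p was 0.255 with array weights, and Gp1bb did not pass without day 7 replicate 2.

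Among regulators of stem cells at day 14, Hoxa9, a homeobox gene active in leukemia, fell from 2400 ± 181 to 1690 ± 137, and Jmjd1c (0.80) and Pbx3 (0.37) rose. Of the 13 measured leukemia-associated homeobox genes and partners, 4 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p 0.37), and the 8 became 5 without control replicate 1, control replicate 2 or day 14 replicate 2. Among the 4 that fell, Eya1, Hoxa3 and Hoxa7 lost their calls with both other scalings. Of 19 quiescence regulators, 5 rose, with Hes1 at 2.60 and Foxo1 at 0.58, and 4 fell, with Pml at -0.75 (5 and 4 adjusted over the list alone, camera adjusted p 0.37). Ndn, which also fell, lost its call with both other scalings. Of 20 p53 target genes, 6 rose, with Pmaip1 at 1.36 and Bbc3 at 1.14, genes that promote cell death, and 5 fell, with Tigar at -0.83 (6 and 5 adjusted over the list alone; camera adjusted p 0.37). Of 17 apoptosis and survival genes, 5 rose, with the survival genes Birc3 at 0.87 and Mcl1 at 0.76, and 4 fell, with Casp8 at -0.83 (5 and 4 adjusted over the list alone, camera adjusted p 0.32). Cflar and Bad, among these 4, lost their calls with both other scalings. Of 19 WNT genes, 5 rose and 4 fell, with Sfrp1 at 0.88 and Myc at -0.78 (5 and 4 adjusted over the list alone, camera adjusted p 0.37), and of 26 niche adhesion and homing genes 8 rose and 5 fell, with the receptor genes Gpr183 at 1.03 and Cxcr4 at 0.49 and the integrin gene Itgb2 at -0.96 (8 and 5 adjusted over the list alone, camera adjusted p 0.23). Apc, which fell in the WNT list, and Epha7, which fell in the niche list, lost their calls with both other scalings. Of 4 sex-linked genes measured, 1 was called at day 14, Eif2s3y at 0.42.

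Control replicate 1 stood apart for erythroid genes: Car1 measured 672 there against 87.0 and 73.9 in the other controls, Klf1 155 against 36.1 and 44.8, and Gata1 203 against 91.7 and 86.3, genes singled out after their values were seen. Of 12 erythroid genes, none was called at day 7 with limma (1 had an unadjusted p below 0.05, 0 adjusted over the list alone; camera adjusted p 0.84), while without that array camera gave 0.0024 in the direction up. At day 14, 3 rose (3 adjusted over the list alone; camera adjusted p 0.37), with 5 without control replicate 1, 6 without control replicate 2 and 5 without control replicate 3. Probe sets of 1 gene did not always move alike. Of 6047 genes with several probe sets that passed the filter on dim probe sets, 246 were called both higher and lower at day 14. These were among 2300 called by at least 2 probe sets, and at day 7 it was 4 of 92.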
